A study of Homo sapiens with 12 samples.

How the data were processed

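Expression was measured on 12 single-colour Illumina BeadChip arrays of A549 cells, 3 for each of 4 plasmids (SEMA5A ICD, ECD, Full and a control plasmid called Empty), with RNA taken 24 h after transfection. Groups and replicate numbers came from the sample titles. Per the labels, the arrays were hybridized with biotin-labelled, amplified RNA; scanner software and bead summary are not given in the sources used here. The deposited table of 47323 probes holds, per array, an intensity on a linear scale with background not subtracted, and a detection p-value in 770 steps that sets each probe against the array's negative controls, as its values show. The authors also deposited log2 values, whose processing is not stated. They equal quantile normalization of the log2 intensities within 5e-09, with no centring, so their scale is known and they carry no added background correction.

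Probes were named from the platform annotation. Of the probes, 30113 had 1 gene symbol, 8 several and 17202 none, and 30074 of those with 1 symbol were matched through their Entrez identifier to the RefSeq gene table of the human assembly GRCh38.p14, which changed 0 symbols. Probes without a symbol, or with several, were tested as unnamed probes. No coordinates were used here.

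Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3 (normexp estimated from the detection p-values, offset 16, quantile normalization, log2). A probe entered when its detection p was under 0.05 on all 3 arrays of at least 1 group, which 18728 did. For each symbol the entering probe with the highest mean over all 12 arrays stood for the gene, leaving 15338 features, 10912 with a symbol and 4426 without. Each comparison was a contrast of group means in 1 limma fit over all 12 arrays with eBayes (8 residual and 6.50 prior degrees of freedom, median SD between arrays of a group 0.145), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all features. The background and offset shrink the fold changes of dim probes. Where all probes of a gene were below background on every array of a group, the change was given as a bound. Of called genes with a symbol, 138 of 428 higher and 67 of 211 lower ones with ICD had another probe to compare. These numbers were 253 of 794 and 125 of 429 with ECD, and 25 of 106 and 7 of 28 with Full. Among those genes, other probes had the same sign for 81.2% of higher and 85.1% of lower genes with ICD. With ECD the shares were 84.6% and 88.0%, and with Full 92.0% and 85.7%. Those named in the text that disagreed are given there. The changes of the other probes were smaller. For higher genes the other probes had a median log2 change of 0.21 with ICD, 0.29 with ECD and 0.49 with Full. The probes used had 0.43, 0.44 and 1.01. For lower genes these medians were -0.25, -0.29 and -0.29 against -0.47, -0.43 and -0.55.

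The designs, the 29 gene lists with their 968 genes, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The 26 lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01, adjusted over the lists, and again with estimated correlations and with fry. The estimate was below 0.01 for the DNA replication, hypoxia, respiratory chain, histone, cholesterol, fatty acid and heat shock lists. Where a call of these lists ended with the estimate, a correlation above the preset one was not the reason. The interferon and sensor lists share members, as do others. Named were the 8 genes with the largest change in each direction in each comparison with Empty, or the 4 in comparisons between constructs, among those with all 3 arrays of a group beyond all 3 of the other. To these were added up to 4 members of each called list with the smallest adjusted p in the list's direction, SEMA5A, PLXNB3 and MET. IFNB1, IFNA1, the IFNL genes, the cell type markers and the genes of 1 construct in the closing paragraphs were chosen after their values were seen.

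For comparisons that share the Empty arrays, unchanged groups of 3 arrays were simulated 100 times for the correlation and in 20 fits for the overlap of calls. The steps were tested on simulated data with 200 of 15338 features changed. For ICD against Empty 76.1% of 1.5-fold and 100% of 2-fold changes were recovered, for ECD 86.3% and 100%, and for Full 82.5% and 98.5%, with 7, 10 and 16 false calls among 15138 unchanged features. Alternatives covered the background correction, offset, scaling, detection filter, probe choice, variance model, array weights, fitted groups, threshold, set test, a block for replicate number and each array left out. The authors' log2 values give the same numbers as the alternative without background correction. Array pairs held 0 identical columns, and 0 columns of sample values were left unused. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.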

Results

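Gene expression was measured in A549 cells, an established line from a human non-small cell lung cancer, 24 h after transfection with plasmids for parts of SEMA5A, a transmembrane semaphorin. Of the 4 groups, 1 received the intracellular domain (ICD), 1 the extracellular domain (ECD), 1 the full-length protein (Full) and 1 a control plasmid (Empty). Each group had 3 single-colour bead arrays, 12 in all, and this number limits the precision. The labels number the arrays of a group as replicates without saying whether they came from separate transfections, so the p-values measure the spread between these arrays, which may be technical. Between 18659 and 20366 of 47323 probes per array were above background at a detection p under 0.05. The 95th percentile of intensity was 9.80 to 10.1 times the background on the ECD arrays and 8.54 to 9.55 times on the other 9, so the ECD arrays were the brightest. Normalized arrays of the same group correlated across genes at r = 0.989 to 0.996, and arrays of different groups at 0.983 to 0.993. The first principal component took 31.5% of the variance. On it the ECD arrays lay at 19.4 to 20.7 and the ICD arrays at 3.44 to 6.38. On the other side were the Full arrays at -18.7 to -3.26 and the Empty arrays at -16.4 to -12.8. On the second, with 15.5%, Full replicate 3 lay at -22.0 against -11.8 and 0.37 for Full replicates 1 and 2.

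SEMA5A itself could not be read on these arrays. Its 2 probes gave 0 values above background among 24, with a lowest detection p of 0.274 and intensities of 85.4 to 103.6. Where these probes lie relative to the cloned parts is not known here, so they check neither the labels nor the amount of any construct, and no fold is given. PLXNB3, the receptor known for SEMA5A, was above background on 0 of 12 arrays. MET, a receptor tyrosine kinase that associates with plexins, was measured on all of them.

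The first comparison asks which genes changed with the intracellular domain alone. Interferon-stimulated genes rose most. IFIT2 and IFIT1, which encode antiviral RNA-binding proteins, were 21.7-fold and 14.9-fold higher with ICD than with Empty (log2 4.44 ± 0.12 and 3.90 ± 0.12, SE, n = 3 arrays each; limma adjusted p = 2.4e-11 and 6.1e-11). HERC5, a ligase for ISG15, was 5.35-fold higher, and ISG15, a ubiquitin-like modifier, 4.51-fold higher. OASL and IFIT3 were not above background on any Empty array and were at least 5.97-fold and at least 5.49-fold higher. Such bounds set the group mean against the lowest normalized signal called above background on the dim arrays, or the probe's own where higher. Of 43 tested genes of the interferon list, 23 rose and 0 fell, with 34 higher when adjusted over the list alone. The median log2 change was 0.66, or 0.67 with 7 members at their bound and 3 that were above background in neither group left out (camera, limma, adjusted p = 1.4e-33; adjusted p = 0.00065 with an estimated correlation). This median of the interferon list depended on the processing, at 0.29 without background correction or with the authors' values and 0.41 with an offset of 50. A second IFIT1 probe differed by only 0.29 on the log2 scale, a second OASL probe by 0.34 and 2 further IFIT3 probes by 1.24 on average.

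Several other groups moved with ICD by smaller amounts. Among immediate early genes, 8 of 32 rose and 0 fell (14 higher and 1 lower when adjusted over the list alone), including the transcription factors EGR1 at 1.61-fold, ETV5 at 1.61-fold and KLF4 at 1.45-fold. Targets of ATF4 and CHOP, transcription factors of the integrated stress response, had 7 of 27 higher (14 when adjusted over the list alone), with SLC3A2, a subunit of amino acid transporters, at 1.43-fold (0.16 on the log2 scale by a second probe). In the focal adhesion and actin list 7 of 49 rose (13 when adjusted over the list alone), with the small GTPase RHOA at 1.37-fold. In the hypoxia and glycolysis list 3 of 31 rose (4 when adjusted over the list alone), among them ADM, which encodes adrenomedullin, at 1.56-fold and the repressor BHLHE40 at 1.52-fold. In the DNA replication list 4 rose and 1 fell of 43 (5 and 1 when adjusted over the list alone), with the ribonucleotide reductase subunit RRM1 at 1.44-fold. Histone genes had 4 lower and 1 higher of 23 (6 and 2 when adjusted over the list alone), with H2AC6 and H2BC5 1.61-fold and 1.59-fold lower. The nuclear respiratory chain list had 1 of 41 lower (0 when adjusted over the list alone), the ATP synthase subunit ATP5F1C by 1.23-fold. These 7 lists passed camera in limma at adjusted p of 1.9e-06 to 0.013. Each of these calls ended with the estimate, at adjusted p = 0.055 to 0.068 with an estimated correlation in limma. For the hypoxia, DNA replication, histone and respiratory chain lists the estimate was 0.0087, -0.0069, -0.023 and 0.0017. These lie below the preset 0.01, so members that vary together do not account for the end of those calls. The nucleic acid sensor list had 6 of 16 higher (6 higher and 1 lower when adjusted over the list alone; camera, limma, adjusted p = 0.0033), with the RNA sensor IFIH1 at 2.60-fold and RIGI at least 2.12-fold higher. Its limma value was adjusted p = 0.068 with an estimated correlation, and 0.38 once the genes it shares with the interferon list were taken out.

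Among the genes most reduced with ICD were TPX2, a spindle assembly factor, at 2.38-fold lower (log2 -1.25 ± 0.13, SE, n = 3; limma adjusted p = 9e-05), the dynein component DYNC2LI1 at 1.78-fold, AK6 at 1.78-fold and PPIB, a chaperone of the endoplasmic reticulum, at 1.75-fold. HNRNPA1P10 and HNRNPA1L2 were 2.85-fold and 2.13-fold lower, but these are near copies of HNRNPA1 and their probes may not tell the copies apart. RHOXF2B, which also has a near copy, was 2.25-fold lower by 1 probe, while the other differed by 0.22 on the log2 scale. MET differed by 0.18 ± 0.09 (limma adjusted p = 0.23). In all, 511 genes or unnamed probes were higher and 411 lower of 15338 tested, 123 and 88 of them by at least 1.5-fold. With median scaling in place of quantile normalization the calls were 324 higher and 167 lower, members called higher fell to 2 in the focal adhesion list and 1 in the DNA replication list, and RHOA and ATP5F1C were not called. Leaving out 1 array gave 492, 314 and 286 calls without Empty replicates 1, 2 and 3 and 429, 525 and 432 without ICD replicates 1, 2 and 3, against 922 with all, and 27 of 44 named genes were called in every such fit. In limma the DNA replication list was no longer called without ICD replicate 2 (adjusted p = 0.062), the hypoxia list without ICD replicate 3 (0.058), RHOA and SLC3A2 without Empty replicate 2 (0.058 and 0.052), RRM1 without Empty replicate 3 (0.053), nor ATP5F1C without any 1 of the 6 (0.079 to 0.16).

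**Figure D1:**
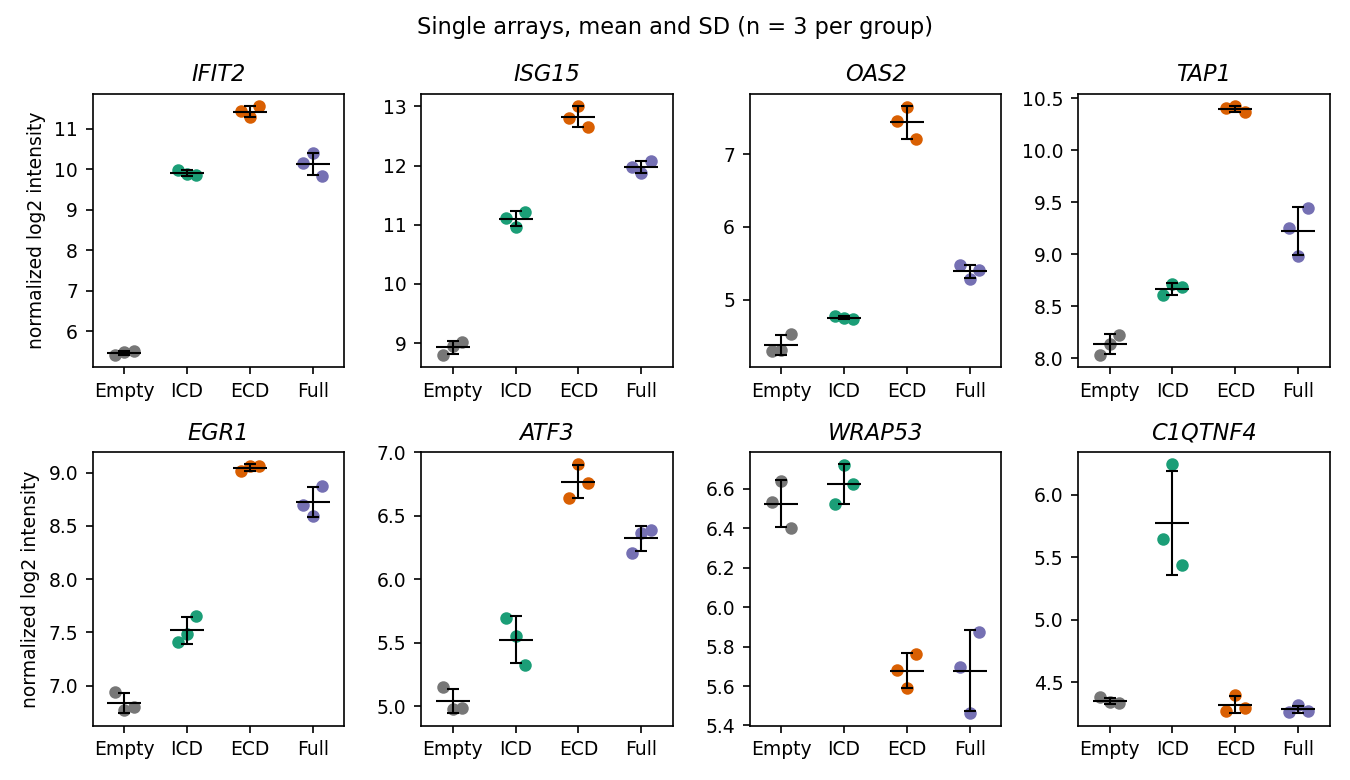
Normalized log2 intensity of 8 genes on each of the 12 arrays by group, with a point per array and the mean and SD of 3 arrays in black. IFIT2, ISG15, OAS2, TAP1, EGR1 and ATF3 were highest with ECD, WRAP53 was lower with ECD and Full than with ICD and Empty, and C1QTNF4 was above background with ICD alone.

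With the extracellular domain the interferon response was larger and broader. IFIT2 was 62.1-fold and IFIT1 53.5-fold higher than with Empty (log2 5.96 ± 0.12 and 5.74 ± 0.12, SE, n = 3 arrays each; limma adjusted p = 2.3e-13 for both). IFI44 was 17.7-fold, ISG15 14.9-fold and IFI6, a mitochondrial protein induced by interferon, 13.1-fold higher, and OASL and IFIT3 were at least 19.8-fold and at least 19.7-fold higher. The other probes of IFIT1, OASL and IFIT3 gave less, at 1.51, 1.35 and 2.49 on the log2 scale. Of the 43 tested interferon genes 42 rose and 0 fell (42 when adjusted over the list alone), with a median log2 change of 2.21, which was also 2.21 with 11 members at their bound (camera, limma, adjusted p = 2.2e-94; adjusted p = 1.2e-05 with an estimated correlation). Without background correction or with the authors' values that median was 1.39. IFNB1, which encodes interferon beta, was above background on 3 of 3 ECD arrays and on none of the other 9, and was at least 2.04-fold higher than with Empty. Probes for IFNA1, IFNL1, IFNL2 and IFNL3 were above background on no array. Genes of antigen presentation on class I molecules rose as well, 9 of 17 higher and 0 lower (9 when adjusted over the list alone). TAP1, which carries peptides into the endoplasmic reticulum, was 4.80-fold, HLA-E 2.39-fold and the immunoproteasome subunit PSMB9 2.15-fold higher. Of the nucleic acid sensors 10 of 16 rose (11 higher and 1 lower when adjusted over the list alone), with IFIH1 at 9.88-fold, RIGI at least 6.48-fold and the kinase EIF2AK2 at 4.22-fold.

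Stress and early response genes also rose with ECD. Immediate early genes had 16 higher and 1 lower of 32 (18 and 1 when adjusted over the list alone), led by EGR1 at 4.64-fold and ATF3 at 3.32-fold. ATF4 and CHOP targets had 14 higher and 1 lower of 27 (17 and 1 when adjusted over the list alone), with DDIT3, which encodes CHOP, at 1.93-fold and PPP1R15A, a phosphatase subunit of the same response, at 1.82-fold. ATF3 belongs to both lists. Of the NF-kB and cytokine list 5 rose and 1 fell of 18 (6 and 1 when adjusted over the list alone). In it the chemokine CCL5 was 3.06-fold, the transcription factor IRF1 2.37-fold, TNFAIP3, an inhibitor of NF-kB signalling, 1.92-fold and NFKBIA, which encodes another, 1.58-fold higher. In the hypoxia list 5 of 31 rose (7 when adjusted over the list alone), with BHLHE40 at 1.90-fold and ADM at 1.74-fold. Antigen presentation, the sensors and these 4 lists passed camera in limma at adjusted p of 2.5e-10 to 0.0075, and at adjusted p of 0.0066 to 0.044 with an estimated correlation. In the DNA replication list 3 of 43 rose (3 when adjusted over the list alone; camera, limma, adjusted p = 0.026, and adjusted p = 0.044 with an estimated correlation), with RRM1 at 1.37-fold. In the nuclear respiratory chain list 4 of 41 fell (4 when adjusted over the list alone; camera, limma, adjusted p = 0.012, and adjusted p = 0.040 with an estimated correlation), with the complex I subunit NDUFA13 1.30-fold lower. In the mitosis list 3 of 48 rose (3 when adjusted over the list alone; camera, limma, adjusted p = 0.021), among them the checkpoint kinase BUB1 at 1.32-fold. That call ended in limma, with adjusted p = 0.40 with an estimated correlation.

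The genes most reduced with ECD changed far less than the interferon genes. NUP43, a nuclear pore protein, was 2.17-fold lower (log2 -1.12 ± 0.21, SE, n = 3; limma adjusted p = 0.0042). The kinase MAP3K12 was 1.92-fold, WRAP53, a telomerase-associated protein, 1.80-fold, the surface aminopeptidase ANPEP 1.74-fold and the calcium-binding proteins S100A13 and S100A3 1.74-fold and 1.72-fold lower. HINT3 was 1.97-fold lower by 1 probe, while its second probe differed by -0.15 on the log2 scale. MET differed by 0.22 ± 0.09 (limma adjusted p = 0.11; 0.020 with median scaling, the lowest of 0.020 to 0.28 over its alternatives). In all, 927 genes or unnamed probes were higher and 823 lower of 15338, 255 and 71 of them by at least 1.5-fold. The split depended on scaling. With median scaling, under which the median of all tested genes was 0.11 higher with ECD on the log2 scale, 2132 were higher and 166 lower. The respiratory chain list was then still called lower (camera, limma, adjusted p = 0.00020, median -0.06), with 0 members called. Members called higher under that scaling were 11 in the DNA replication list, 11 in the hypoxia list and 6 in the mitosis list. Leaving out 1 array gave 1011, 875 and 595 calls without Empty replicates 1, 2 and 3 and 804, 788 and 869 without ECD replicates 1, 2 and 3, against 1750 with all, and 37 of 49 named genes were called in every such fit. In limma the DNA replication list was not called without ECD replicate 1 or 2 (adjusted p of up to 0.069), RRM1 without Empty replicate 3 or ECD replicate 1 (0.065 and 0.053), NDUFA13 without Empty replicate 3 (0.067), nor BUB1 without Empty replicate 2 or 3 or ECD replicate 1 (0.061, 0.075 and 0.077).

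**Figure D2:**
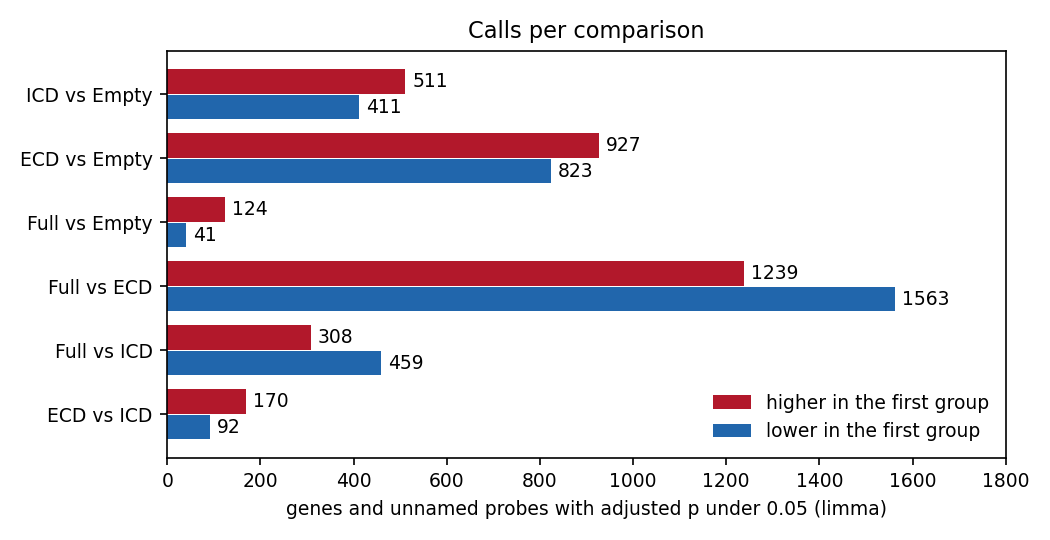
Number of genes and unnamed probes called at a limma adjusted p under 0.05 in each of the 6 comparisons, with red bars for those higher and blue bars for those lower in the group named first. Full against Empty had the fewest, 124 higher and 41 lower, and Full against ECD the most, 1239 higher and 1563 lower.

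The third comparison asks what the full-length protein did, and again interferon genes led. IFIT2 was 25.3-fold and IFIT1 20.8-fold higher than with Empty (log2 4.66 ± 0.12 and 4.38 ± 0.12, SE, n = 3 arrays each; limma adjusted p = 1.1e-11 for both). ISG15 was 8.30-fold, IFI44 7.75-fold and HERC5 5.77-fold higher, and OASL and IFIT3 were at least 9.71-fold and at least 8.78-fold higher. Other probes of IFIT1, OASL and IFIT3 were 0.75, 0.77 and 1.76 higher on the log2 scale. In the interferon list 35 of 43 rose and 0 fell (42 when adjusted over the list alone), with a median log2 change of 1.12, or 1.16 with 10 members at their bound and 1 that was above background in neither group left out (camera, limma, adjusted p = 1.1e-93; adjusted p = 1.3e-05 with an estimated correlation). The same median was 0.65 without background correction or with the authors' values. TAP1 was 2.13-fold and HLA-E 1.59-fold higher, among 3 of 17 antigen presentation genes that rose (9 when adjusted over the list alone). IFIH1 was 3.23-fold and RIGI at least 2.44-fold higher, among 5 of 16 sensors that rose (7 when adjusted over the list alone). Immediate early genes had 6 of 32 higher (10 when adjusted over the list alone), with EGR1 at 3.70-fold, ATF3 at 2.43-fold and KLF4 at 1.64-fold. Of ATF4 and CHOP targets 3 of 27 rose (5 when adjusted over the list alone), which were ATF3, DDIT3 at 1.70-fold and PPP1R15A at 1.59-fold. CCL5, at 2.23-fold, was the 1 of 18 NF-kB and cytokine genes that rose (8 higher and 1 lower when adjusted over the list alone). Antigen presentation, the sensors, the immediate early genes, the ATF4 and CHOP targets and the cytokines passed camera in limma at adjusted p of 9.9e-10 to 0.00029, and at adjusted p of 0.0086 to 0.037 with an estimated correlation.

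A further 4 lists were called with Full only under the preset correlation. In the hypoxia list 2 of 31 rose (2 when adjusted over the list alone; camera, limma, adjusted p = 0.014; adjusted p = 0.068 with an estimated correlation), ADM at 1.61-fold and BHLHE40 at 1.44-fold. The mitosis list had a median log2 difference of -0.14 with 0 of 48 genes called (0 when adjusted over the list alone; camera, limma, adjusted p = 0.00027; adjusted p = 0.30 with an estimated correlation). Fatty acid synthesis genes had a median of -0.14 with 0 of 16 called (1 higher and 2 lower when adjusted over the list alone; camera, limma, adjusted p = 0.012; adjusted p = 0.054 with an estimated correlation). Cholesterol synthesis and uptake genes had a median of -0.09 with 0 of 20 called (0 when adjusted over the list alone; camera, limma, adjusted p = 0.040; adjusted p = 0.12 with an estimated correlation). Among single genes, WRAP53 was 1.80-fold lower (log2 -0.85 ± 0.11, SE, n = 3; limma adjusted p = 0.00075), MAP3K12 1.70-fold and the surface peptidase MME 1.65-fold lower. MET differed by -0.18 ± 0.09 (limma adjusted p = 0.35). In all, 124 genes or unnamed probes were higher and 41 lower of 15338, 88 and 9 of them by at least 1.5-fold, and 85 higher and 10 lower with median scaling, under which BHLHE40 and the cholesterol list were not called. A fit of only these 2 groups called 65, with DDIT3 and BHLHE40 not among them. Leaving out 1 array gave 105, 82 and 85 calls without Empty replicates 1, 2 and 3 and 103, 462 and 106 without Full replicates 1, 2 and 3, against 165 with all, and 23 of 32 named genes were called in every such fit. In limma the mitosis and hypoxia lists were not called without Full replicate 3 (adjusted p = 0.083 and 0.087), the cholesterol list without Empty replicate 3 or Full replicate 2 (up to 0.15), nor BHLHE40 without any 1 of the 6 but Empty replicate 1 (0.054 to 0.17).

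**Figure D3:**
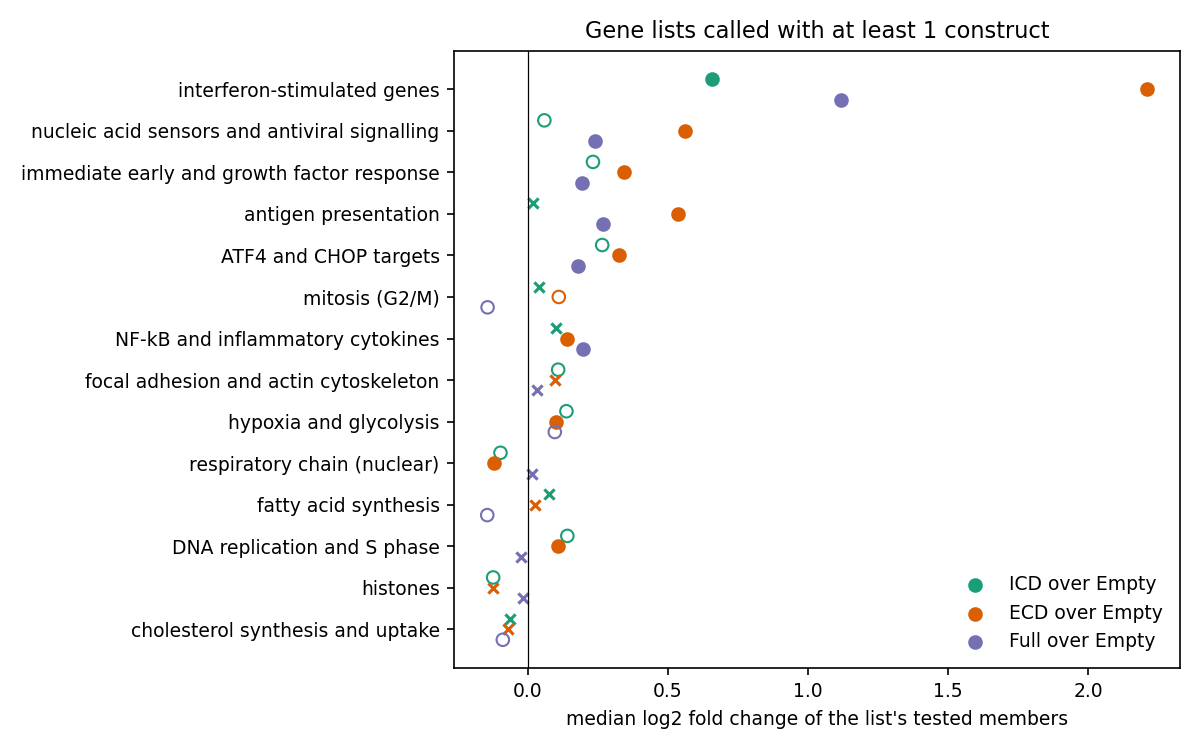
Median log2 fold change over Empty of each gene list called with at least 1 construct, with 1 point per construct. Filled circles mark lists called also with an estimated correlation, open circles lists called only with the preset one and crosses lists not called; the interferon list lay at 0.66 with ICD, 1.12 with Full and 2.21 with ECD.

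Set against each other directly, the domain constructs differed most in interferon genes, which were higher with ECD than with ICD. OAS2, an enzyme that senses double-stranded RNA, was 6.47-fold, IFI27 6.37-fold, IFI44L 5.46-fold and USP18, a protease that removes ISG15, 5.19-fold higher with ECD (log2 2.69 ± 0.11, 2.67 ± 0.14, 2.45 ± 0.10 and 2.38 ± 0.13, SE, n = 3 arrays each; limma adjusted p of 4.4e-09 to 3.5e-08). A second IFI44L probe differed by 0.33 on the log2 scale. In the interferon list 42 of 43 were higher (43 when adjusted over the list alone), with a median log2 difference of 1.53 (camera, limma, adjusted p = 2.6e-126; adjusted p = 3.9e-06 with an estimated correlation). Antigen presentation had 7 higher and 1 lower of 17 (11 and 1 when adjusted over the list alone), the sensors 8 higher of 16 (9 higher and 1 lower when adjusted over the list alone) and the NF-kB and cytokine list 3 higher of 18 (5 when adjusted over the list alone). In limma these 3 lists had camera adjusted p of 5.9e-14 to 5.5e-05, and adjusted p of 0.0016 to 0.0086 with an estimated correlation. ATF4 and CHOP targets (3 higher of 27, and 4 when adjusted over the list alone), immediate early genes (4 of 32, and 7), mitosis genes (1 of 48, and 1) and heat shock proteins (0 of 23, and 3) were called at camera adjusted p of 0.0015 to 0.029 in limma. Those calls ended at adjusted p = 0.10 to 0.36 with an estimated correlation in limma. In the other direction, WRAP53 was 1.93-fold and MAP3K12 1.90-fold lower with ECD, and C1QTNF4, a secreted C1q-related protein, was at least 2.16-fold lower. PLIN5, a lipid droplet protein, was 1.95-fold lower (limma adjusted p = 0.044), a call lost without ICD replicate 2 or 3 or ECD replicate 2 or 3 (0.12 to 0.21). It was also lost with no detection filter, with trend and robust eBayes and with replicate number as a block. MET differed by 0.05 ± 0.09 (limma adjusted p = 0.85). In all 170 genes or unnamed probes were higher with ECD and 92 lower, 262 in total, or 280 and 20 with median scaling, and the total was 159 and 139 without ECD replicates 1 and 2.

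Between Full and ICD the interferon genes were higher with Full, by less. IRF7, a transcription factor of the interferon response, was 2.05-fold and the restriction factor IFITM1 2.04-fold higher with Full (log2 1.04 ± 0.11 and 1.03 ± 0.11, SE, n = 3 arrays each; limma adjusted p = 0.00048 for both), and EGR1 was 2.30-fold higher. In the interferon list 25 of 43 were higher and 0 lower (31 when adjusted over the list alone), with a median log2 difference of 0.50 (camera, limma, adjusted p = 2.4e-25; adjusted p = 0.0018 with an estimated correlation). Antigen presentation had 4 of 17 higher (10 higher and 1 lower when adjusted over the list alone) and the NF-kB and cytokine list 1 of 18 (1 when adjusted over the list alone). DNA replication genes had 7 of 43 lower with Full (10 when adjusted over the list alone), fatty acid synthesis genes 1 of 16 lower (3 when adjusted over the list alone) and respiratory chain genes 0 of 41 called (0 when adjusted over the list alone), with a median of 0.09. These 5 lists had camera adjusted p of 0.00023 to 0.014 in limma, and adjusted p of 0.025 to 0.049 with an estimated correlation. The mitosis list (1 higher and 3 lower of 48, and 2 and 7 when adjusted over the list alone), the focal adhesion list (1 and 4 of 49, and 2 and 5) and the histones (2 and 0 of 23, and 2 and 0) had camera adjusted p of 0.0035 to 0.019 in limma. Those 3 calls ended at adjusted p = 0.49, 0.066 and 0.064 with an estimated correlation in limma. WRAP53 was 1.93-fold and CNST 1.83-fold lower with Full, and C1QTNF4 at least 2.11-fold lower. MET was 1.28-fold lower with Full (log2 -0.36 ± 0.09; limma adjusted p = 0.034). That call was lost with median scaling, in a fit of only these 2 groups and without any 1 of the 6 arrays but Full replicate 2. The limma adjusted p was 0.074 to 0.088 in those fits with 1 array left out. In all 308 genes or unnamed probes were higher and 459 lower, 767 in total, or 90 and 199 with median scaling. A fit of only these 2 groups called 22. With median scaling, members called lower were 4 in the DNA replication list, 1 in the mitosis list and 0 in the fatty acid and focal adhesion lists. Members called higher were then 2 in antigen presentation and 0 in the histones. Leaving out 1 array gave 194, 193 and 429 calls without ICD replicates 1, 2 and 3 and 226, 1624 and 188 without Full replicates 1, 2 and 3.

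Between Full and ECD the interferon genes were lower with Full. OAS2 was 4.15-fold, IFI27 3.46-fold, IFI44L 3.35-fold and IFIH1 3.06-fold lower (log2 -2.05 ± 0.11, -1.79 ± 0.14, -1.74 ± 0.10 and -1.61 ± 0.13, SE, n = 3 arrays each; limma adjusted p of 2.8e-07 to 6.1e-06). A second IFI44L probe differed by -0.54. In the interferon list 40 of 43 were lower and 0 higher (41 when adjusted over the list alone), with a median log2 difference of -1.15 (camera, limma, adjusted p = 1.2e-44; adjusted p = 0.00022 with an estimated correlation). Mitosis genes had 22 of 48 lower and 0 higher (24 when adjusted over the list alone; 14, 26 and 10 lower without Full replicates 1, 2 and 3), the sensors 10 lower and 2 higher of 16 (10 and 2 when adjusted over the list alone) and DNA replication genes 10 of 43 lower (13 when adjusted over the list alone). Antigen presentation had 6 lower and 1 higher of 17 (7 and 2 when adjusted over the list alone), ATF4 and CHOP targets 4 of 27 lower (4 when adjusted over the list alone) and respiratory chain genes 3 higher and 1 lower of 41 (1 and 0 when adjusted over the list alone). These 6 lists had camera adjusted p of 2e-05 to 0.042 in limma, and each call ended, at adjusted p = 0.052 to 0.20 with an estimated correlation. NUP43 was 2.18-fold and the transcriptional regulator NACC1 1.94-fold higher with Full, and the small RNA gene RNU105C at least 3.21-fold higher. MET was 1.32-fold lower with Full (log2 -0.40 ± 0.09; limma adjusted p = 0.0077). In all 1239 genes or unnamed probes were higher and 1563 lower, 2802 in total, or 258 and 2898 with median scaling. Under that scaling 27 mitosis genes, 14 DNA replication genes, 11 sensors, 8 antigen presentation genes and 11 ATF4 and CHOP targets were lower. Respiratory chain genes then had 3 higher and 0 lower. The total was 1661, 1532 and 1676 without ECD replicates 1, 2 and 3 and 1535 without Full replicate 3.

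Many genes moved the same way with several constructs. Together 73 genes or unnamed probes were higher with all 3 constructs than with Empty, 22 of them in the interferon list, and 10 were lower. ICD and ECD shared 318 higher and 249 lower calls, against 30.9 and 22.1 for independent lists of the same lengths. The shared numbers were 77 and 12 for ICD and Full, against 4.13 and 1.10, and 109 and 16 for ECD and Full, against 7.49 and 2.20. Simulated unchanged groups against the same controls shared 0 calls, but they hold no changes to call, so this sets no level for lists of these lengths. Fold changes correlated across genes, which are not independent replicates, at r = 0.70 for ICD and ECD, 0.51 for ICD and Full and 0.45 for ECD and Full, against 0.50 in that simulation. Their covariances were 0.0481, 0.0251 and 0.0281 against a simulated 0.00789, so 0.0402, 0.0172 and 0.0202 remained. Part of this was the interferon list, without which r was 0.68, 0.45 and 0.30 and the covariances were 0.0385, 0.0186 and 0.0146. The 3 control arrays were not split between the constructs, and part of the excess may come from them. ICD and ECD arrays also lay apart from Full and Empty arrays on the first principal component. The labels state no batch, so a share of technical origin in this was not tested. Calls shared by ICD and ECD, 567 in total, were 300, 190 and 155 without Empty replicates 1, 2 and 3, 290, 311 and 303 without ICD replicates 1, 2 and 3, and 299, 313 and 314 without ECD replicates 1, 2 and 3. Those shared by ICD and Full, 89 in total, were 46 without Empty replicate 2 or 3, 58 without ICD replicate 1 or Full replicate 1 and 144 without Full replicate 2, and those shared by ECD and Full, 125 in total, were 80, 73 and 83 without Empty replicate 2, Empty replicate 3 and Full replicate 1.

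**Figure D4:**
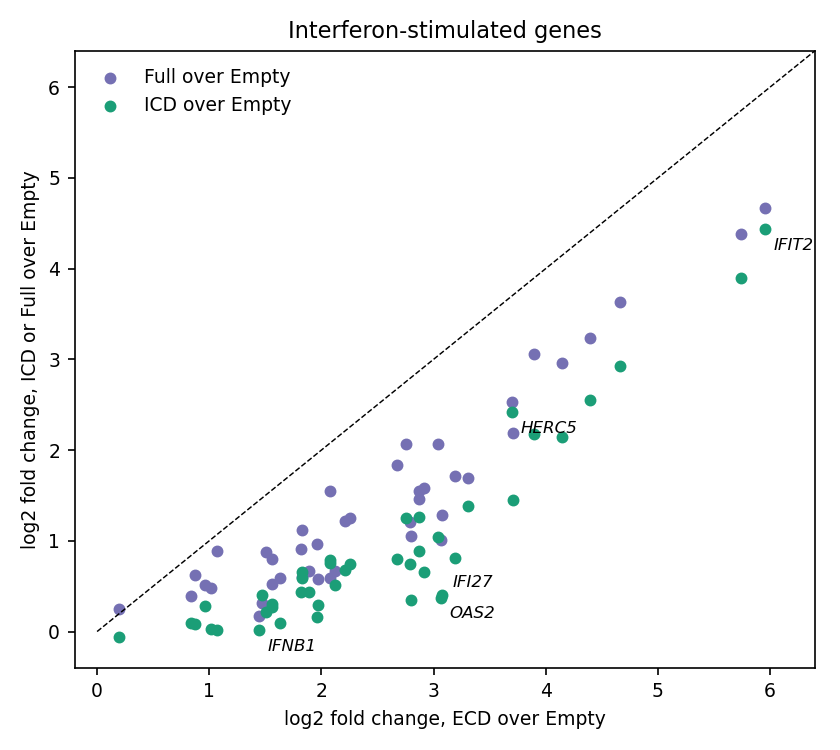
Log2 fold change over Empty of the 43 tested interferon genes, with ECD on the horizontal axis and ICD (green) or Full (purple) on the vertical axis, each point 1 gene and the dashed line marking equal change. Nearly all points lie under the line, and the change was in the order ECD, Full, ICD for 40 of the 43.

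Of the 26 lists with at least 5 tested members, 12 were called with no construct against Empty by camera with the main settings. These were endoplasmic reticulum chaperones, p53 targets, apoptosis regulators, mesenchymal genes, epithelial genes, extracellular proteases, semaphorins with plexins and neuropilins, NRF2 targets, heat shock proteins, TGF-beta targets, alveolar lineage genes and ribosomal proteins. Their lowest camera adjusted p in limma was 0.057, for ribosomal proteins with ICD. That list was called lower with median scaling, at camera adjusted p = 0.00024 with ICD and 6.8e-07 with ECD in limma, and with ICD at 0.019 without background correction or with the authors' values. In limma fry, which does not set a list against the other genes, called 7 of the 12 with at least 1 construct at adjusted p under 0.05, namely p53 targets, apoptosis, epithelial, semaphorin, heat shock, alveolar and ribosomal genes. With 1 array left out, camera in limma called alveolar genes without Empty replicate 2 with ECD (adjusted p = 0.042) and with Full (0.044), and without Full replicate 1 (0.017), and TGF-beta targets with Full without Empty replicate 2 (0.017). The alveolar list shares LAMP3 with the interferon list. With interferon members taken out, its camera adjusted p in limma on all arrays went from 0.088 to 0.61 with ECD. With Full it went from 0.12 to 0.50. Median, mean and camera direction differed in sign for some lists that were not called, among them mitosis, apoptosis, NRF2, heat shock and TGF-beta genes with ICD, proteases with ECD, and ribosomal and respiratory chain genes with Full. Few markers of other cell types passed the detection filter. Of 15 fibroblast markers 2, FBLN1 and COL1A1, were tested and 0 were called. Of 13 endothelial markers 1 was tested, ESAM, which was above background on 3 ECD and 2 ICD arrays and on 0 others and was higher with ECD (limma adjusted p = 0.034). Of 18 leukocyte markers 3, HLA-DRA, CD68 and CD14, were tested, and CD68 was 0.35 higher on the log2 scale with ECD (limma adjusted p = 0.026), and 0 were called with ICD or Full.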

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

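All 3 tests of the mitosis genes in this part were chosen after the result was seen. SH3GLB2, an endophilin-like protein, moved in opposite directions with the domain constructs. Against Empty it was 0.34 higher on the log2 scale with ICD (limma adjusted p = 0.044) and changed by -0.41 with ECD (0.013), a difference of -0.75 between ECD and ICD (0.0002). The unnamed probe ILMN_1669657 did likewise, at 0.58 with ICD (limma adjusted p = 0.049), -0.53 with ECD (0.047) and -1.11 between them (0.0011). These were the 2 features called in opposite directions with ICD and ECD. Both calls with ICD and the unnamed probe's call with ECD lay close to the threshold of 0.05. Whether they hold with 1 array left out is not given here.

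Mitosis genes as a list had medians of 0.11 with ECD and -0.14 with Full against Empty, with 3 and 0 of 48 members called, and in limma both list calls ended with an estimated correlation (adjusted p = 0.40 and 0.30), that for Full also without Full replicate 3 (0.083). The direct median difference between Full and ECD was -0.31 (camera, limma, adjusted p = 2e-05), a call that also ended with an estimated correlation (adjusted p = 0.20). A single Full array as the whole source of this difference is argued against. The median was -0.28, -0.33 and -0.22 without Full replicates 1, 2 and 3. It does not decide the fall below Empty, where the list lay at -0.10, -0.02 and -0.22 on Full replicates 1, 2 and 3. The brighter ECD arrays remain open as an explanation. With median scaling the list still lay at -0.28 relative to the median of all genes. Taking off a single median does not remove a shift that differs with intensity, so that value cannot decide. That members vary together between arrays of a group remains open as a candidate explanation for the small p, given that value of 0.20. A difference in cycling between the constructs was not tested and also stays open.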

How the results depend on the processing

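The interferon list taken out of the other lists was an alternative chosen after seeing the data, and the others were planned. Counts of calls depended on the processing. Without background correction (also the authors' values) 1617 were called for ICD against Empty and 1501 for Full against ICD, with an offset of 50 1510 and 1385, and with trend and robust eBayes 1444 and 1342. Median scaling gave 491, 95 and 289 for ICD, Full and Full against ICD. Array weights gave 1537, 3257, 695, 4328 and 1577 for ICD, ECD, Full, Full against ECD and Full against ICD. Fits of only the groups compared, with fewer arrays behind the spread, gave 2718, 65, 1593 and 22 for ECD, Full, Full against ECD and Full against ICD. The main fit gave 1750, 165, 2802 and 767. Full arrays were the least alike, with median r within the group of 0.991 to 0.993 against 0.994 to 0.996 in other groups. The main fit does not let the spread differ between groups. The 1.5-fold threshold, stricter by construction, left 211, 326, 97, 438, 108 and 146 for ICD, ECD, Full, Full against ECD, Full against ICD and ECD against ICD. Lists called fell to 1 for ICD and 6 for Full with estimated correlations, and fry called 19 for ECD. The correlation of ICD and ECD was 0.73 and their overlap 1042 without background correction or with the authors' values, and the correlation was 0.67 with no detection filter. Except where the construction shows it, the cause was not tested. With 1 array left out, calls were 286 to 525 for ICD, 595 to 1011 for ECD, 82 to 462 for Full, 1532 to 3731 for Full against ECD, 188 to 1624 for Full against ICD and 139 to 194 for ECD against ICD. Lists called were then 8 to 9, 9 to 11 and 8 to 12 for ICD, ECD and Full. Correlations were 0.65 to 0.73 for ICD and ECD, 0.44 to 0.57 for ICD and Full and 0.33 to 0.52 for ECD and Full, and overlaps 155 to 314, 46 to 144 and 73 to 161. SEMA5A stayed at 0 values above background. For named genes, 2253 of 2480 verdicts were unchanged, 223 lost the call, 4 gained it (MET with ECD) and 0 turned sign. The replicate number as a block gave 829, 1704, 140, 2812, 670 and 247 calls for ICD, ECD, Full, Full against ECD, Full against ICD and ECD against ICD. Same-numbered arrays correlated at -0.085 to 0.118 over 18 pairs, 1 above 0.1, so the numbers were not taken to pair the arrays. A slide block was not run because the files give no slide. Genes below background on every array of a group, such as IFNB1 with Empty, are given as a bound, and SEMA5A as unread, for reasons not tested.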

Other observations

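The tests of the interferon genes and of shared domains in this part were chosen after the results were seen, and the splits of the arrays were planned. Some genes differed most with 1 construct, being called in the same direction against Empty and against both other constructs. With ICD these were 10 higher and 12 lower. C1QTNF4 was above background on the 3 ICD arrays and on 0 of the other 9 (limma adjusted p = 8.7e-05 against Empty), and HOXC4, a homeobox factor, was 0.45 higher on the log2 scale. TPX2 was among those lower. With ECD there were 123 higher, 40 of them in the interferon list, and 15 lower. Outside that list PMAIP1, a BH3-only apoptosis gene, was 1.77 higher on the log2 scale than with Empty and HES4, a Notch-related repressor, 1.67 higher. The largest changes outside it also included TAP1 of the antigen presentation list and DDX60 and ADAR of the sensor list. A gene outside the interferon list may thus still belong to the same response. With Full there were 4 higher and 6 lower. The vault RNA gene VTRNA1-1 was 1.19 higher, and GJB1, a gap junction protein, 0.60 higher.

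Probes without a symbol made up 28.9% of tested features. They were 48.7% of the lower and 16.2% of the higher calls with ICD, 47.9% and 14.3% with ECD and 31.7% and 14.5% with Full.

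Interferon genes were higher with every construct than with Empty. Over 3 other normalizations, 1 of which equals the authors' values, the lowest median log2 change of the list was 1.39 with ECD and 0.65 with Full, both above the bar of 0.58, which argues against normalization there, but 0.29 with ICD, where the list was still called and the part that processing plays in the size stays open. Leukocytes in the cultures are argued against, since PTPRC, LYZ, TYROBP and FCER1G gave 0 values above background on the ECD arrays (PTPRC and LYZ were each above it on 1 of 12 arrays). Of the 3 tested members of the planned leukocyte list, though, 1, CD68, was called higher with ECD. The argument therefore rests on the former genes alone. Plasmid preparation or amount, rather than the encoded protein, cannot be told apart from it, because each construct had its own plasmid and SEMA5A had 0 probe values above background to measure expression. An effect of the encoded protein stays open on the same ground.

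Interferon genes also differed in the share of their ECD change reached with ICD, as seen in the 27 that were above background on all Empty arrays and rose by over 0.58 on the log2 scale with ECD. IFIT2 reached 74.5% and HERC5 65.4%, against 8.20% for PLSCR1 and 1.64% for IFITM3. A response in constant proportion is argued against under the main normalization, the only one used for this test. The SD of the residuals around it was 4.67 median standard errors of an ICD change, without the error of the ECD change. A single response rising with the size of the change remains open at 1.59 such standard errors. The share correlated with the ECD change at r = 0.86 across these genes, which are not independent replicates. A further hypothesis is that genes which IRF3 induces without interferon may respond more fully to ICD: 5 textbook targets had a median share of 65.4% against 28.4% for 22 others (two-sided permutation p = 0.00070). The background filter left out the targets OASL at 62.8%, IFIT3 at 58.1%, CXCL10 at 17.7% and IFNB1 at 1.24%. IFIT2 and IFIT1, among the 5, had the largest ECD changes of the list (log2 5.96 and 5.74). Being a target is thus not separate from the size of the change. The targets were also listed after the shares were seen, so this stays undecided.

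The hypothesis that constructs with a domain in common share genes stays undecided. Outside the interferon list 16 genes or probes followed ECD and Full together, differing from both Empty and ICD, among them WRAP53 and MAP3K12, which were lower. The other 14 were higher, among them TAP1 and PSMB9 of the antigen presentation list. The call of PSMB9 with Full against Empty was lost without Empty replicate 1, Empty replicate 2 or Full replicate 1 (limma adjusted p = 0.070, 0.098 and 0.067). It was also lost without background correction, with the authors' values and in a fit of only the 2 groups compared. SCARNA13 was the 1 that followed ICD and Full, and 144 followed ICD and ECD, which by their names have no domain in common. In the interferon list the numbers were 25, 0 and 0. These counts depend on the lengths of the call lists, and Full against Empty had 165 calls where ICD and ECD had 922 and 1750, so they cannot be set against each other.

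Each comparison was refitted on its 6 arrays alone for all 10 splits into groups of 3. The real split gave 915, 2718, 65, 1593, 22 and 270 calls for ICD, ECD and Full against Empty, Full against ECD, Full against ICD and ECD against ICD. The highest of the other splits gave 0 each time, so 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05.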
